A study of Macaca mulatta with 5 samples.

How the data were processed

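Prefrontal cortex of 4 rhesus macaques aged 0.4, 9, 22 and 26 years was profiled for H3K4me2. Per the labels' protocols, about 200 mg of tissue went into each immunoprecipitation with an antibody against dimethylated H3 lysine 4. The input came from tissue of 7 animals pooled, cross-linked in 1% formaldehyde for 15 min and sonicated to an average of 300 to 500 bp, with no immunoprecipitation. Each age has 1 library from 1 animal, and the groups are the ages given in the labels.

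The deposited data were 1 file of aligned reads per library and 1 island table for the whole series. Each line of a read file gives the position and strand of a read of 35 bases. No position and strand occurred more than once within a file, so repeated reads had been removed before deposit. The aligner and the genome build are not given in the sources used here. SICER, which joins enriched windows into islands, is the tool named in the submitters' processing notes, and the deposited table's name gives a window of 200 bp, a gap of 400 bp and a false discovery rate of 0.001. The table has no header, and its columns were identified by testing them on the reads. They hold the island's bounds, the deposited count of pooled H3K4me2 reads, the deposited count of input reads, the authors' p-value against the input, the authors' fold (the ratio of pooled H3K4me2 to input scaled by their totals) and the adjusted p-value. The pooled count was within 2 reads of the sum counted here for 98.5% of islands, and the input count was equal for 86.6%. The scale built into the fold column, 2.75, equals the pooled reads without repeats (38954655 of 39611430) over the input reads. The islands were therefore called once on the 4 libraries together, so no list of islands per age was used, and the authors' fold serves here only to describe and group islands.

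Reads were counted per island after moving the 5' end 75 bp towards the 3' end. The autosomes held 8402719 reads at 0.4 yr, 9405440 at 9 yr, 10155000 at 22 yr, 10810296 at 26 yr and 13738020 in the input. For ratios after subtraction of background, the input reads of an island, scaled by background reads, were taken off its count and the rest was set to at least 1 read. Background reads were those in 215567 autosomal bins of 10 kb that overlap no island, and they made up 60.9%, 54.4%, 52.0% and 52.6% of the autosomal reads in order of age and 74.8% in the input. Shares of reads carry exact Clopper-Pearson intervals at 95%. At the depth of these libraries the intervals of the autosomal shares are narrower than 0.1 percentage points, whereas at an island with 50 reads in a pair of libraries the counting interval of a log2 ratio spans over 1 unit. Reads carry no molecular identifiers, so all intervals and limits cover counting error only.

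The age trend was fitted with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with age in years as a number, an intercept, TMM scaling over island counts, edgeR's filter on low counts with a minimum of 10, autosomal islands only, and Benjamini-Hochberg adjustment at 0.05. The 4 libraries leave 2 residual degrees of freedom, and the test sets the age slope against the scatter of 4 animals around a straight line, not against the spread among animals of one age. The test also draws each island's variance towards that of the other islands, with 33.8 prior degrees of freedom. Most of the weight in a p-value's variance thus comes from other islands, not from that island's own 4 counts. Pairs of ages were compared without a test, as log2 ratios of TMM-scaled counts with a pseudocount of 0.5 reads and an exact conditional binomial interval, over islands with at least 50 reads in the pair. Counting error alone was simulated with 20 draws per pair. A fold against 0 reads was computed against 3 reads. Levels near an island were counted in reads outside islands within 20 kb on each side. Islands were also called here per library at an equal depth of 8402719 autosomal reads, with the window, gap and false discovery rate of the deposited table and a score floor that random reads exceed 1000 times. The trend test was tested on simulated counts for 58049 islands, 200 of them changed, and the caller on 300 simulated islands, all found with 0 calls elsewhere. Other tools were DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

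The design, the first set of alternatives and the naming rule were fixed before the data were examined. The rule names, for the trend, the 5 islands with the smallest p in each direction where fewer than 5 pass, with 4 per direction printed by position when no annotation is at hand. For each pair of ages it names the 5 islands with the largest log2 ratio in each direction among those with at least 50 reads, of which the first few are printed, and it names the 5 islands with most reads per kb. The island chr1:4525201-4528600 falls under the trend and the pair part of the rule, and chr5:181734001-181734600 under those and the reads per kb. The islands chr1:4539801-4546000, chr1:126366401-126367800, chr7:12791001-12795000 and chr5:37427601-37428000 are each named in more than 1 pair.

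The alternatives were other scalings (DESeq2 size factors, total reads, background reads), other tests (DESeq2, limma-voom), other codings of age, no filter, a shift of 200 bp, all chromosomes, islands at a false discovery rate of at most 1e-10, windows of 2 kb, and leaving out each library. Equal depth, islands called here, background scaling without each library and groupings of islands by the 22 yr and 26 yr libraries were added after seeing the data. The planned tests at promoters and on 19 gene lists, and a correction for GC content, need an annotation or genome of the build of the files and were not run. Keeping repeated reads changes nothing, since the files hold 0 repeated positions.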

Results

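Dimethylation of lysine 4 on histone H3 (H3K4me2), a chromatin mark found at promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the prefrontal cortex of rhesus macaques. The series holds 4 H3K4me2 libraries, from animals aged 0.4, 9, 22 and 26 years with 1 animal at each age, and 1 input library of unenriched chromatin DNA pooled from 7 animals, among them the 4 used for H3K4me2. The deposited reads numbered 8595726 at 0.4 yr, 9605954 at 9 yr, 10368182 at 22 yr, 11041568 at 26 yr and 14148769 in the input. No age has a replicate, so a difference between libraries is a difference between animals as well as between ages, and every interval given here covers counting error only. The labels give no sex. The X chromosome held 3.14, 3.05, 3.05 and 3.07 reads per 100 autosomal background reads at 0.4, 9, 22 and 26 yr, against 3.70 in the pooled input, and the comparisons below use the autosomes.

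H3K4me2 was concentrated in 59189 deposited islands, which are stretches of enriched sequence called by the authors on the 4 libraries together. Of these, 58414 lay on autosomes and 775 on the X chromosome. They covered 199.5 Mb, with a median width of 2600 bp, and 1925 of them spanned at least 10 kb. Chromosomes 19 and 16 were the most densely marked, with 55.5 and 50.8 islands per Mb, and chromosomes 5 and 17 the most sparsely, with 8.40 and 13.0. The median enrichment over input in the authors' deposited table was 2.34-fold. No annotation of the genome build of these files was used here, so islands are named by position in that build, and which gene, exon, intron or promoter each one touches was not analysed here.

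Of the 5 islands with the highest read density, 4 were at most 800 bp wide and 1 spanned 7400 bp. They were chr11:129489601-129490000 with 545.0 reads per kb over the 4 libraries, chr8:2203201-2203600 with 462.5, chr16:78179401-78180200 with 431, chr1:140038001-140045400 with 403 and chr5:181734001-181734600 with 368. In 4 of these 5 the input was also dense, at 70.0 to 97.8 reads per kb against a median of 7.5 over the autosomal islands, and the authors' fold was 1.31 to 1.60. The exception was the chromosome 16 island, with 20.0 input reads per kb and an authors' fold of 5.88.

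The first comparison asked how much of each library lay in these islands, given the series' question of whether H3K4 methylation builds up through postnatal development and aging. A larger share of the autosomal reads lay in islands in each of the 3 older animals than in the infant. The share was 24.7% at 0.4 yr (exact Clopper-Pearson 95% interval 24.66 to 24.72), 30.6% at 9 yr (30.61 to 30.67), 33.8% at 22 yr (33.73 to 33.79) and 33.2% at 26 yr (33.18 to 33.24). In the input the same islands held 11.2% (11.23 to 11.26), so the enrichment over input was 2.20, 2.72, 3.00 and 2.95-fold in order of age. Relative to reads in 10 kb bins free of islands, island reads were 1.39 times the 0.4 yr level at 9 yr, 1.60 times at 22 yr and 1.56 times at 26 yr. The intervals of the 4 libraries do not overlap, but with 1 animal per age the spread between animals of one age is unknown. The 2 oldest animals differed by 0.554 percentage points, with the lower share at 26 yr.

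**Figure D1:**
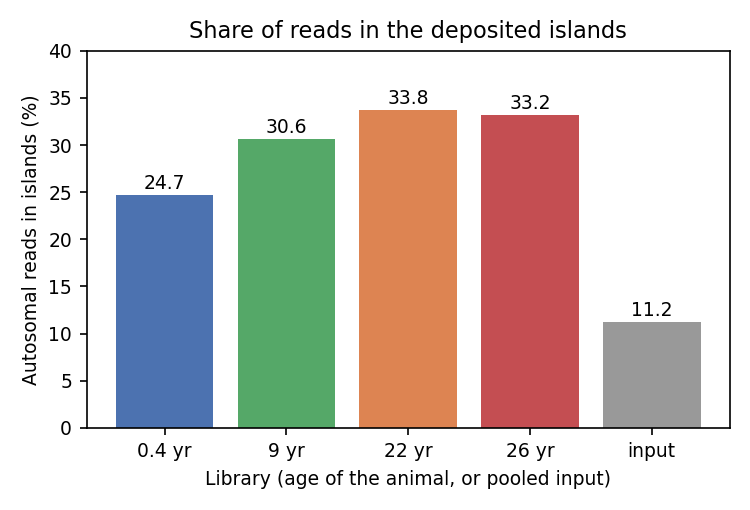
Bars show the percentage of autosomal reads in the deposited islands (vertical axis) for each of the 4 H3K4me2 libraries, by age of the animal in years, and for the pooled input. The shares are 24.7% at 0.4 yr, 30.6% at 9 yr, 33.8% at 22 yr, 33.2% at 26 yr and 11.2% in the input, with 1 library per bar and exact 95% counting intervals narrower than 0.1 percentage points.

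The higher level in the older animals was spread over the genome. Scaled to background reads, the summed island reads of each of the 20 autosomes exceeded the 0.4 yr level in all 3 older libraries. The log2 ratio ran from 0.40 on chromosome 10 to 0.53 on chromosome 19 at 9 yr, from 0.64 on chromosome 4 to 0.75 on chromosome 19 at 22 yr, and from 0.55 on chromosome 10 to 0.74 on chromosome 5 at 26 yr. Wide islands differed more than narrow ones. For the 1812 islands over 10 kb the log2 ratio to 0.4 yr was 0.59, 0.79 and 0.68 at 9, 22 and 26 yr, and for the 21715 islands of up to 2 kb it was 0.38, 0.59 and 0.60. With this scaling the median island was 0.41, 0.59 and 0.56 above its 0.4 yr level on the log2 scale. Under scaling by the trimmed mean of M values (TMM), which sets the typical island to no change, those medians were -0.01, -0.01 and -0.01.

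Strongly enriched islands differed more from the infant level than weakly enriched ones, by an amount that shrank once background was subtracted. The autosomal islands were divided into 4 equal groups by the authors' fold over input. With background scaling, the median log2 ratio of 26 over 0.4 yr was 0.29, 0.41, 0.62 and 0.85 from the weakest to the strongest group, that of 22 over 0.4 yr was 0.38, 0.45, 0.64 and 0.83, and that of 9 over 0.4 yr was 0.26, 0.33, 0.45 and 0.56. Weak islands hold more background. After subtraction of input reads scaled to background, the medians in the same order were 0.61, 0.70, 0.90 and 1.03 at 26 yr, 0.78, 0.77, 0.92 and 0.998 at 22 yr, and 0.55, 0.58, 0.66 and 0.69 at 9 yr. Without subtraction, in the strongest group 96.9% of the 14604 islands were above their 0.4 yr level at 26 yr, and 75.7% of the 14638 in the weakest group. TMM shifts all ratios of a library by the same amount, which leaves the order of the groups as it is, and places the weakest group below the infant level (-0.16, -0.22 and -0.28 at 9, 22 and 26 yr) and the strongest above it (0.15, 0.23 and 0.28). The authors' fold draws on the same libraries, and with islands grouped by the 22 yr library's own fold the 26 over 0.4 yr medians ran from 0.33 to 0.85 with background scaling. No p-value was computed for these medians, because each age is 1 library and islands are not replicates. The differences between the weakest and the strongest group after subtraction are set against a bound under the other observations.

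**Figure D2:**
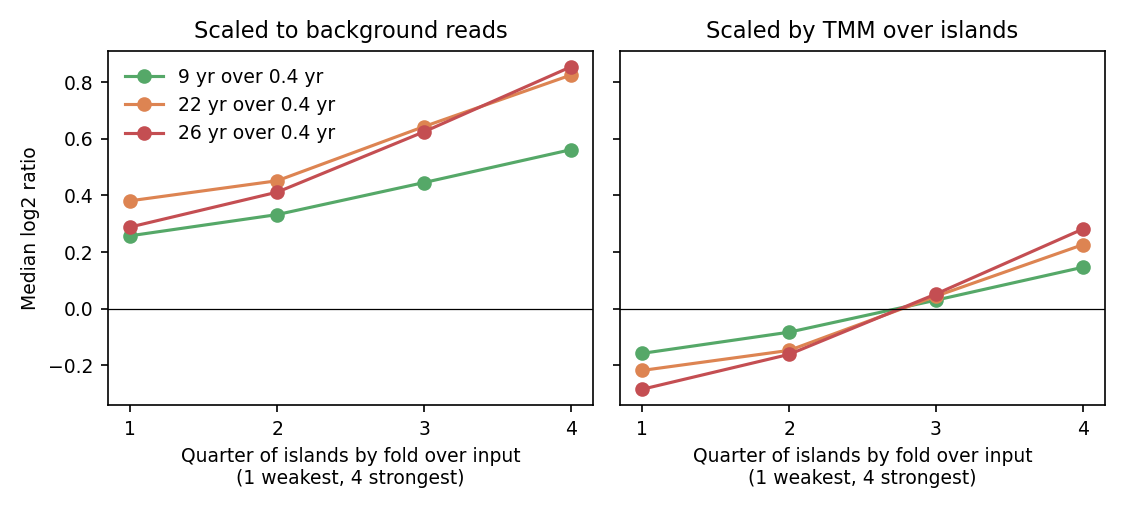
Points give the median log2 ratio over the 0.4 yr library (vertical axis) of islands in 4 equal groups by the authors' fold over input, from the weakest (1) to the strongest (4), for the 9, 22 and 26 yr libraries, scaled to background reads on the left and by TMM over islands on the right. The 26 yr medians climb from 0.29 to 0.85 with background scaling and from -0.28 to 0.28 with TMM.

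The next comparison asked which islands changed steadily with age. With TMM scaling, which measures each island against the typical island, edgeR's quasi-likelihood test of a linear trend in years called 0 rising and 0 falling islands of 58049 tested at a false discovery rate of 0.05. At an unadjusted p under 0.05 it gave 2058 rising and 1989 falling islands. DESeq2 and limma-voom also called 0 in each direction, with 341 rising and 187 falling and with 1809 rising and 2104 falling at the unadjusted level. When libraries were instead scaled to background reads, edgeR called 687 rising islands and 1 falling island, and with total reads 18 rising and 0 falling. All 18 were among the 687. Of the 687, 516 belonged to the strongest of the 4 groups by fold and 11 to the weakest. This split does not separate island strength from selection or from read number. The authors' fold draws on the same libraries, and no grouping by the infant library's own fold was made. The strongest group also held more reads, 8.66% of the autosomal reads at 0.4 yr against 4.89% in the weakest. In simulated data the TMM trend recovered 75% of 4-fold and 11% of 2-fold changes, with 6 of the unchanged islands called. The simulation gave every island the same dispersion, steady changes with age and no correlation with its neighbours, so these rates may not hold for the real islands. These counts moved with single libraries. With TMM, rising and falling calls were 7 and 3 without the 0.4 yr library, 11 and 10 without the 9 yr library, 4 and 0 without the 22 yr library, and 5 and 9 without the 26 yr library. With background scaling they were 11 and 1 without the 0.4 yr library, 8738 and 11 without the 9 yr library, 8 and 0 without the 22 yr library, and 292 and 1 without the 26 yr library.

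The 5 islands with the smallest p in each direction did not pass with TMM. Among those with higher levels in older animals was chr1:4525201-4528600, whose TMM-normalised read counts were 25.0, 23.9, 38.2 and 95.7 in order of age, a fitted log2 change of 2.02 between the youngest and oldest animal (edgeR adjusted p = 0.205). Its neighbour chr1:4535601-4537800 had normalised counts of 16.7, 25.0, 29.3 and 83.1 (fitted log2 change 2.14, edgeR adjusted p = 0.205). Without the 26 yr library their slopes of 0.08 log2 units per year became 0.03. Reads outside islands within 20 kb of them were also highest at 26 yr, at 15, 9, 20 and 37 for the first and 8, 2, 5 and 14 for the second. The island chr7:57835201-57836400 went from 5.55 to 18.7, 27.5 and 47.8 (fitted log2 change 2.43, same adjusted p), while reads outside islands within 20 kb of it numbered 30, 80, 123 and 136 in order of age. The island chr4:29682001-29686200 went from 45.8 to 63.4, 114 and 112 (fitted log2 change 1.37), with 126, 143, 138 and 129 flanking reads. The authors' fold over input was only 1.43 and 1.64 for the chromosome 1 islands, under the median of 2.34. It was 8.06 and 4.57 for the chromosome 7 and chromosome 4 islands. At a low fold much of an island's count is background. These 4 islands passed with background scaling, at edgeR adjusted p-values of 4.5e-05, 4.6e-05, 0.00016 and 0.0018 in the order given. Each call under that scaling ended without 1 of the libraries, in fits with 1 residual degree of freedom. Without the 26 yr library the slopes of the chromosome 1 islands fell from 0.096 and 0.101 to 0.057 and 0.058 log2 units per year (edgeR adjusted p = 0.148 and 0.174). Other calls ended while the slope changed less. Without the 0.4 yr library the second chromosome 1 island had a slope of 0.104 (edgeR adjusted p = 0.0789), the chromosome 7 island 0.085 against 0.113 (0.938), and the chromosome 4 island 0.062 against 0.074 (0.816). Without the 22 yr library the chromosome 4 island had 0.069 (0.195).

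Among the islands with lower levels in older animals, chr1:15881801-15885800 had normalised counts of 72.2, 33.3, 23.97 and 16.8 in order of age (fitted log2 change -1.92, edgeR adjusted p = 0.205) and chr14:118476201-118479800 had 66.7, 34.3, 23.1 and 16.8 (-1.84, same adjusted p). The island chr2:108247201-108250200 had 56.9, 35.4, 11.5 and 20.1 (-1.87, edgeR adjusted p = 0.452). The densely covered chr5:181734001-181734600 had 147, 30.2, 33.7 and 40.3, with a fitted log2 change of -1.85 (edgeR adjusted p = 0.205). It was the only island that fell with background scaling, at an adjusted p of 0.0427. Without the 22 yr library the call ended (0.363) with the slope nearly unchanged, -0.046 against -0.048. With TMM its slope of -0.07 log2 units per year rested on the infant, and without the 0.4 yr library it was 0.02 with TMM and 0.03 with background scaling. The authors' fold over input was 1.42, 1.63, 3.67 and 1.46 for these islands in the order given. Those at 1.42, 1.63 and 1.46 belong to the weakest group by fold, whose medians TMM places below the infant level.

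Postnatal development was addressed by the 0.4 and 9 yr libraries. With TMM scaling, 386 of the 31672 islands with at least 50 reads in the pair were over 2-fold higher at 9 yr and 291 were over 2-fold lower. Counting error alone gave 70.0 and 43.5 in simulated pairs. The island chr20:944401-946600 had 12 reads at 0.4 yr and 91 at 9 yr, a log2 ratio of 2.45 (exact 95% counting interval 1.63 to 3.51), with 29 and 68 flanking reads. The island chr16:53378601-53380800 had 56 and 321 reads (2.09, interval 1.69 to 2.54) with nearly level flanks of 89 and 92 reads. Its count was 120 at 22 yr and 272 at 26 yr. In the other direction, chr5:181734001-181734600 went from 106 to 29 reads (-2.27, interval -2.93 to -1.68) and chr4:130745401-130746600 from 39 to 13 (-1.97, interval -3.03 to -1.07). With background scaling 2565 islands were over 2-fold higher and 43 over 2-fold lower, and with total reads 1277 and 85.

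Aging was addressed by setting the 22 and 26 yr libraries against 9 yr. With TMM scaling, 304 islands were over 2-fold higher at 22 yr and 348 over 2-fold lower, of 36681, against 58.5 and 47.6 from counting error alone. At 26 yr 184 were higher and 172 lower, of 37636, against 71.7 and 52.4. The background-scaled counts were 773 and 137 at 22 yr and 417 and 64 at 26 yr. In both comparisons the first island by ratio was chr1:126366401-126367800, which held 0 reads at 9 yr, 31 at 0.4 yr, 57 at 22 yr and 81 at 26 yr. Against a limit of 3 reads in the 9 yr library, its normalised level was at least 13.8-fold higher at 0.4 yr, at least 16.2-fold higher at 22 yr and at least 21.8-fold higher at 26 yr. These limits leave out the counting error of the other library, and the lower ends of the exact 95% counting intervals of the log2 ratio were 3.67 at 22 yr and 4.11 at 26 yr. The island chr7:12791001-12795000 had 16 reads at 9 yr, 128 at 22 yr (log2 ratio 2.73, interval 2.02 to 3.62) and 100 at 26 yr (2.30, interval 1.56 to 3.20), but 34 at 0.4 yr, and its flanks held 39 reads at 9 yr, 116 at 22 yr and 119 at 26 yr. At 26 yr chr1:4539801-4546000 stood at 363 reads against 53 at 9 yr (2.45, interval 2.05 to 2.91), and chr5:37427601-37428000 at 46 against 4 (3.06, interval 1.76 to 5.15). Lower levels were found at chr1:15242801-15246000, from 41 reads at 9 yr to 11 at 22 yr (-2.08, interval -3.24 to -1.14), and at chr8:125412001-125415200, from 63 to 19 (-1.93, interval -2.78 to -1.20). At 26 yr they were found at chr2:185955001-185957200, from 70 to 20 (-2.09, interval -2.91 to -1.38), and at chr20:1128801-1131600, from 40 to 12 (-2.01, interval -3.11 to -1.09).

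**Figure D3:**
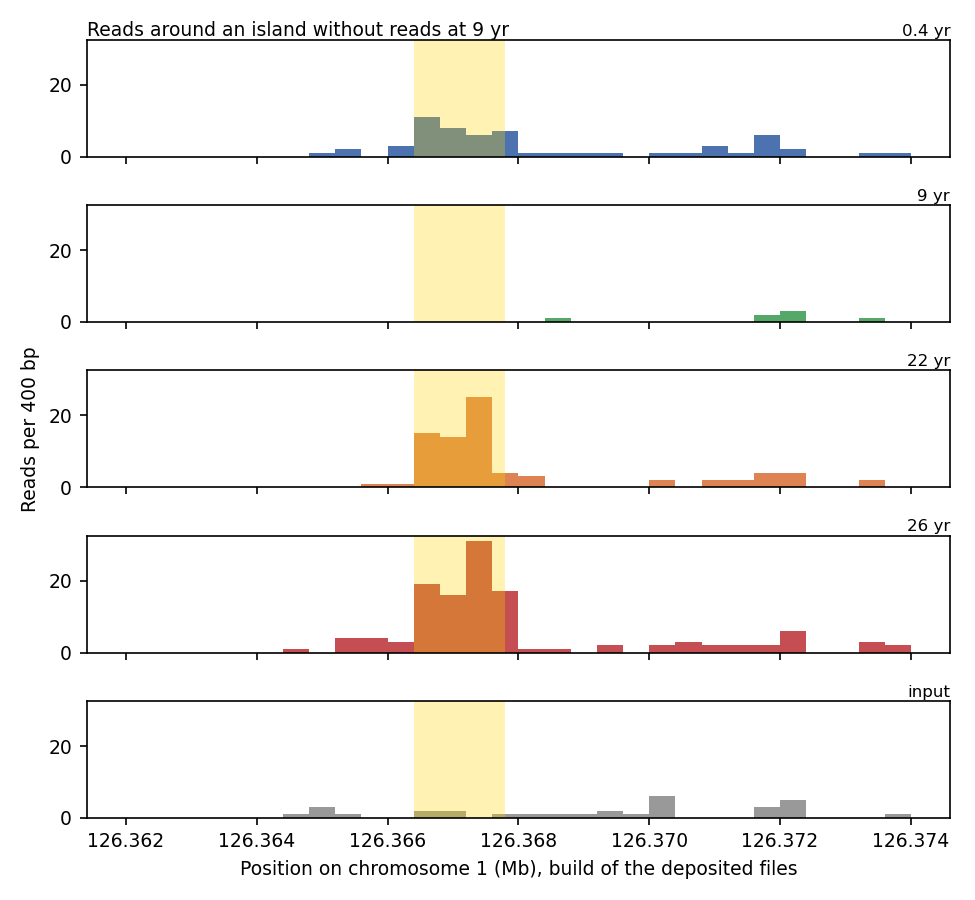
Reads per 400 bp (vertical axis) along chromosome 1 in Mb, in the build of the deposited files, for the 4 H3K4me2 libraries by age and the pooled input, with the island chr1:126366401-126367800 shaded. The island holds 31, 57 and 81 reads at 0.4, 22 and 26 yr and 0 at 9 yr.

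The 22 and 26 yr animals, the only pair close in age, gauged how far animals differ when age differs little. With TMM scaling 318 of 39212 islands were over 2-fold higher at 26 yr and 284 over 2-fold lower, against 59.5 and 52.0 from counting error alone. Together these made up 1.54% of the islands with enough reads, against 2.14% for 0.4 to 9 yr, 1.78% for 9 to 22 yr and 0.946% for 9 to 26 yr, and 2.60% and 2.35% for 0.4 yr against 22 and 26 yr. The standard deviation of the log2 ratio across islands was 0.38 for this pair, 0.41 for 0.4 to 9 yr, 0.39 for 9 to 22 yr, 0.35 for 9 to 26 yr, and 0.44 for 0.4 yr against both 22 and 26 yr, where counting error alone gave 0.28 to 0.30. With at least 200 reads in the pair, 5 of 9604 islands were over 2-fold higher and 12 lower between 22 and 26 yr, against 44 and 3 of 4434 between 0.4 and 9 yr. The island chr4:165828001-165829200 had 7 reads at 22 yr and 51 at 26 yr (log2 ratio 2.70, interval 1.64 to 4.17), chr5:37427601-37428000 had 6 and 46 (2.76, interval 1.63 to 4.38), and chr1:4539801-4546000 had 68 and 363 (2.33, interval 1.96 to 2.73). Lower at 26 yr were chr10:58671801-58673600, with 41 and 9 reads (-2.21, interval -3.50 to -1.21), and chr4:120080001-120082400, with 50 and 16 (-1.70, interval -2.64 to -0.89).

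**Figure D4:**
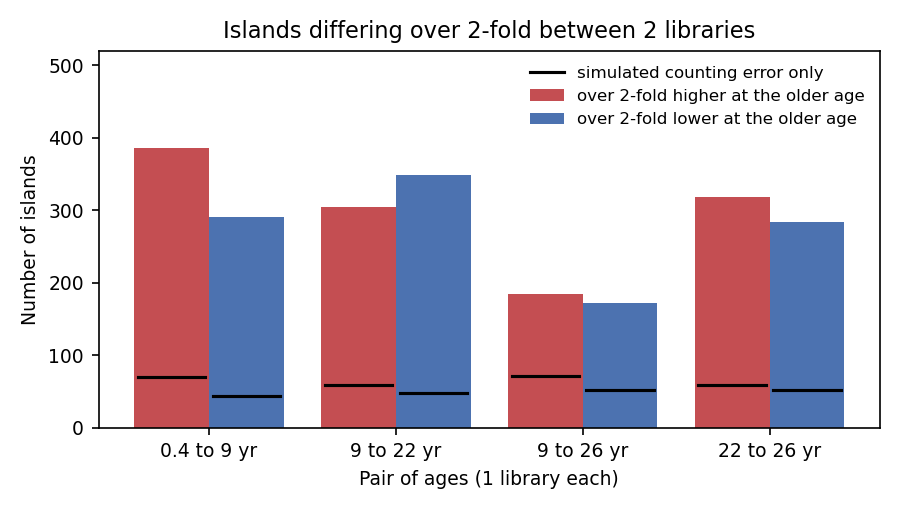
Bars count the islands (vertical axis) that were over 2-fold higher or lower at the older age in each pair of libraries with TMM scaling, and black lines mark the counts that simulated counting error alone gives. The pair of near ages, 22 to 26 yr, has 318 higher and 284 lower islands, beside 386 and 291 for 0.4 to 9 yr.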

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

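The X chromosome was left out of the comparisons because the labels give no sex, yet its islands held clear H3K4me2 signal. Of the X reads, 9.82% lay in X islands at 0.4 yr, 14.1% at 9 yr, 16.6% at 22 yr and 16.7% at 26 yr, against 2.22% in the input. All 4 lower counting bounds, the lowest at 9.69%, lie above the upper bound of the input, 2.27%. The order of the first 3 ages matches that on the autosomes, and the 22 and 26 yr values overlap within their intervals of 16.5 to 16.8% and 16.5 to 16.9%. Age and animal are not separable here, and no explanation of the X values was tested.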

How the results depend on the processing

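The higher share of reads in islands in all 3 older animals than at 0.4 yr held under every alternative run, while the calls of the age trend depended on the scaling. Alternatives that used equal depth, islands called here, background scaling with a library left out, or strength from the 22 yr library were chosen after seeing the data. In order of 0.4, 9, 22 and 26 yr and input, the share in percent was 24.1, 30.0, 33.0, 32.5 and 11.1 with a shift of 200 bp. It was 19.4, 25.0, 27.9, 27.5 and 7.80 for islands at a false discovery rate of at most 1e-10, and 24.4, 30.3, 33.4, 32.9 and 10.98 over all chromosomes. It was 23.4, 29.0, 32.1, 31.6 and 9.92 for islands called here on the 4 libraries at equal depth, 15.3, 17.2, 19.6, 19.5 and 4.82 for islands of the 0.4 yr library alone, and 16.5, 21.5, 24.2, 25.8 and 6.48 for islands of the 26 yr library alone. The 26 yr share exceeded the 22 yr share only with islands of the 26 yr library, which favour that library by construction.

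The trend counts were 0 rising and 0 falling with edgeR on TMM and with DESeq2 size factors, DESeq2, limma-voom, rank of age, no filter, a shift of 200 bp, all chromosomes, stricter islands, 2 kb windows, equal depth and equal-depth islands. They were 18 rising with total reads, 687 rising and 1 falling with background scaling, 7 falling with log2 age, and 13 rising and 9 falling with the 0.4 yr animal set against the older 3. Unlike TMM, total-read and background scaling keep the larger share of reads in islands of the older animals in each ratio. That shift is measured and not set by the scaling, and it favours rising calls. Age and immunoprecipitation efficiency cannot be told apart as its source. For the age codings the cause was not tested. Leaving out 1 library gave 4 to 11 rising and 0 to 10 falling calls with TMM, and, with background scaling, 11, 8738, 8 and 292 rising and 1, 11, 0 and 1 falling calls without the 0.4, 9, 22 and 26 yr library, and the cause was not tested. A fit without 1 library has 1 residual degree of freedom. Of 205 alternative values for the slopes of the 10 named islands, 154 kept their direction and side of the threshold, 49 passed it and 2 reversed, namely chr5:181734001-181734600 without the 0.4 yr library, at 0.0221 log2 units per year with TMM, where its lowest value was -0.101 without the 26 yr library, and at 0.0323 with background scaling.

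Counts of islands over 2-fold also followed the scaling. In order of higher and lower, they were 1277 and 85 for 0.4 to 9 yr with total reads and 2565 and 43 with background scaling, 543 and 187 and then 773 and 137 for 9 to 22 yr, and 318 and 85 and then 417 and 64 for 9 to 26 yr. The 22 to 26 yr counts stayed within 1.5 times of their TMM values. With at least 200 reads per pair, where fewer islands qualify and counting error is smaller, the counts were 44 and 3 of 4434 for 0.4 to 9 yr, 9 and 8 of 7697 for 9 to 22 yr, 3 and 3 of 8171 for 9 to 26 yr, and 5 and 12 of 9604 for 22 to 26 yr. The weakest group of islands by fold lay above its 0.4 yr level with background scaling and below it with TMM, at -0.16, -0.22 and -0.28 for 9, 22 and 26 yr, because TMM sets the typical island to no change.

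No paired analysis was possible because each age has 1 library. The promoter trend, the gene list trend and the GC correction were not run for lack of an annotation or genome of the build of the files, and the alternative with all reads as deposited was not run because the files hold 0 repeated positions. Depth limits single islands, since 31672 to 39212 of the 58414 autosomal islands reached 50 reads in a pair of ages.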

Other observations

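Tests chosen only after the result was seen are the immunoprecipitation test, the 22 and 26 yr parts of the common-factor test and the test of one copy number over the chromosome 1 cluster. The islands called per library were also added after seeing the data.

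When islands were called on each library separately at an equal depth of 8402719 autosomal reads, the infant cortex gave the fewest. There were 27392 islands at 0.4 yr, 33537 at 9 yr, 36126 at 22 yr and 35354 at 26 yr. They covered 83.8, 117, 122 and 115 Mb, with mean widths of 3059, 3489, 3376 and 3251 bp. Of the 0.4 yr islands, 79.3% were overlapped by those of the 9 yr library, 82.7% by those of the 22 yr library and 82.1% by those of the 26 yr library. In the other direction, 62.0%, 59.97% and 61.6% of the islands of the 9, 22 and 26 yr libraries overlapped an island of the infant. Between 95.8% and 97.3% of each set overlapped a deposited island. Across all 58414 autosomal islands, log2 levels of the 3 older animals correlated with one another at Pearson's r of 0.920 to 0.932, and each of them with the infant at 0.897 to 0.898. The unenriched input correlated with the infant at 0.813 and with the older animals at 0.739 to 0.784, so much of r is not particular to the mark. The infant library also had the fewest reads in islands, 2074468 against 2881458 at 9 yr, and its lower r was not separated from counting error. These values are across islands, which are not independent replicates.

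Differences between single libraries were correlated between neighbouring islands, for a cause that was not tested. Among 35494 islands with at least 100 reads, the 0.4 to 9 yr ratio of an island correlated with that of the next island at r of 0.179 and rho of 0.173, and the 22 to 26 yr ratio at r of 0.216 and rho of 0.214. The highest r in 100 shuffles was 0.0126 and 0.0106. The 0.4 to 9 yr and 22 to 26 yr ratios, which share no library, correlated at r of 0.0943 and rho of 0.0928 across islands. The naming rule picked 40 ratios from 36 islands, so some islands count more than once. Flanking reads, scaled to background reads, differed in the same direction for 34 of these ratios, and by over 0.5 on the log2 scale for 9. The same share was not computed for other islands.

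The 4 ages can be assigned to the 4 libraries in 24 orders. With TMM the real order called 0 islands and the highest other order 27, so all 24 orders necessarily call at least as many as the real one, and this says nothing about chance. With background scaling 2 of the 24 orders, the real one included, called at least the real 688, so chance is not excluded. The other was the order with the 22 and 26 yr ages exchanged, with 3182 calls, several times the real count. That order follows the share of reads in islands of the 4 libraries.

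The first pattern is the higher share of reads in islands in the 3 older animals. Islands called on pooled libraries might favour the deeper, older libraries, but in islands called from the 0.4 yr library alone that library still had the lowest share, 15.3% against at least 17.2%, which argues against this as the whole cause. A common factor on every island would leave the weakest and strongest islands with the same ratio once background is subtracted. At 26 yr their medians differed by 0.41 on the log2 scale (SE 0.01), and by 0.39 with islands grouped by the 22 yr library, beyond a bound of 0.2. That bound was set in advance for 9 yr only. At 9 yr they differed by 0.14 (SE 0.01), also with islands grouped by the 22 yr library, under the bound, but by 0.20 with islands grouped by the 26 yr library, at the bound. At 22 yr they differed by 0.22 (SE 0.01), and by 0.24 with islands grouped by the 26 yr library, both slightly beyond the bound. Each SE is taken over islands of single libraries, which are not replicates, so it does not cover the spread between animals. At 9 yr the planned grouping falls under the bound, and a grouping added after seeing the data lies at it. At 22 yr both values are close to the bound, and the spread between animals is unknown. A common factor thus stays open at 9 and 22 yr. Immunoprecipitation efficiency of single libraries cannot be told apart from age, because no age has a repeat library and the only near-age pair, 22 and 26 yr, differed by 0.554 percentage points; an increase of H3K4me2 with age stays open and untested beside it.

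The second pattern is the island chr1:126366401-126367800, which held 0 reads in the 9 yr library and 169 in the other 3. A stretch of DNA absent from the 9 yr animal may account for this, since the 9 yr library also had no read in the 1761 bp to the left of the island, where the other 3 libraries held 20 reads, more than the bound set in advance. The pooled input held 5 reads in that stretch, so few background reads would be expected there at 9 yr. That stretch was itself picked as free of 9 yr reads. In the 500 bp on each side, a width set in advance, the 9 yr library had 0 reads and the other 3 had 7 on the left and 7 on the right. The input had 0 reads in both, so these 14 may be the shoulder of the mark rather than background, and they do not separate absent DNA from an absent mark. Outside islands within 20 kb the 9 yr library held 50 reads, against 113, 103 and 147 at 0.4, 22 and 26 yr. Further left, no library had a read as far as the next 9 yr read, so the extent on that side is unknown. The input is a pool of 7 animals, so it cannot show a loss in 1 animal. A sequence difference from the reference that stops reads from aligning would look the same and was not tested, nor was a difference of age.

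The third pattern is a cluster of 7 islands at chr1:4498401-4566200, spanning 67.8 kb, with island reads at 26 yr at 2.27 times the TMM-scaled level of the other 3 libraries pooled. Reads between the islands were also higher there, 2.20 times per background read (exact interval 1.48 to 3.24; 50 reads at 26 yr against 22, 14 and 26), as extra copies of DNA in the 26 yr animal would give. The island ratio is TMM-scaled and this ratio is not, so their closeness does not show that both rose alike. One number of copies over the whole stretch would raise its islands alike, but their log2 ratios ran from 0.56 (upper bound 0.73) to 2.18 (lower bound 1.93), a span of 1.62. Of 3213 runs of 7 neighbouring islands elsewhere with at least 168 reads each, 2 spanned as much, and without the highest island 43 of 3749 runs of 6 spanned the remaining 1.17. The next highest island, chr1:4535601-4537800, was also picked by the naming rule, so that span still rests on a selected island. The island chr1:4529201-4535000, not picked by the rule, had a log2 ratio of 1.57 (lower bound 1.28), above the upper bound of the lowest island. These bounds cover counting error only, and that last gap was not set against runs elsewhere. Islands elsewhere also differ among themselves, with a median span of 0.59 in runs of 7 and 0.55 in runs of 6. The rarity of spans as wide as in the cluster argues against a single copy number as the whole cause, within the limit that the cluster was selected. Copies of part of the stretch, or copies beside a change in the mark, stay open. The interval of the reads between islands includes 1.5, and a broad spread of the mark beyond island bounds would raise the same reads. The input was also dense over the cluster, at 9.07 reads per kb against 5.07 over the autosomes, with 574 reads in its islands and 41 between them. The input is pooled, so this density cannot be assigned to the 26 yr animal. A change with age stays open and untested.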
